A study of Rattus norvegicus with 6 samples.

How the data were processed

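Achilles tendons of rats on post-natal day 1 and day 7 were profiled on an Affymetrix rat expression array, with 3 samples of each age and RNA from at least 2 animals in each sample. Per the labels' protocols, tendons were isolated under a dissecting microscope, RNA was purified on columns, and labelled RNA was made with a linear amplification kit. The sex of the animals, the hour of harvest and the way animals were assigned to pools are not given in the sources used here.

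The deposited table held 1 intensity per probe set and array, on a linear scale, and the authors' processing notes name MAS5 and RMA without a role or a version for either. Which of the tools made the deposited intensity values, and the background correction and scaling, are not given in the sources used here. The distributions were close on the 6 arrays but not identical, and they differed with age. The 75th percentiles lay between 94.3 and 95.9 on day 1 and between 84.1 and 91.8 on day 7. The 25th percentiles lay between 6.91 and 7.08 on day 1 and between 7.32 and 7.90 on day 7. A remaining difference of scale is thus confounded with age and can move many genes, which the normalization alternatives address.

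The values were transformed to log2(value + 1) and not normalized further. Of 31099 probe sets, 57 controls were left out and 31042 tested. A platform annotation paired 20826 of the tested probe sets with 1 gene symbol, 436 with several and none with the other 9780, which were tested without a name. Symbols were looked up by gene identifier in a RefSeq gene table of the rat assembly GRCr8, where 20758 of the 20826 matched and 0 needed an update. No genome coordinates are given, because no build is named for the array values. A gene was represented by the probe set with the highest mean log2 value over the 6 arrays among those naming it alone, which gave 14217 genes, 4525 of them with several probe sets. No gene had probe sets called in opposite directions, and 52 called genes had another probe set with a change of the opposite sign.

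Day 7 was compared with day 1 by limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested. The threshold was an adjusted p under 0.05. Log2 changes are day 7 minus day 1 on the log2(value + 1) scale, and SE is the moderated standard error. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, for the 30 of 31 lists with at least 5 measured genes, with Benjamini-Hochberg adjustment over the 30. The lists held 912 entries, of which 787 were measured, and were written from textbook knowledge of tendon and of neighbouring tissues. The design, the lists, the rule for named genes and the processing alternatives were fixed before the data were examined, except where a choice is said to be later.

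The named genes were the 10 largest rises and 10 largest falls among called genes whose day 7 arrays all lay on one side of all day 1 arrays, up to 4 genes of each list with the smallest adjusted p, and the fixed set Scx, Mkx, Egr1, Tnmd, Fmod, Thbs4, Comp, Tnc, Dcn, Col1a1, Col1a2, Col3a1 and Fos. Further members of a list were named after their values were seen, where they complete a count or set a call beside its counterpart: Igf2bp1, Igf2bp2, Igf2, H19, Eya1, Cidec, Cfd, Cebpa, Lpl, Lipe, Ucp1, Mbp, Acta1, Myh8, Ryr1, Myh7, Tef, Bmal1, Npas2, Clock, Cry1, Nfil3 and Fkbp5. Kcna2 and Tspyl4, which are in no list, were named because they were still called without day 7 replicate 1. Mkx was not analysed here.

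The fit was tested on simulated intensities for all 14217 genes, with the real means and the moderated variances of the fit. In the simulation 200 genes were changed and the 35 measured genes of the mitosis list shifted by -0.5 on the log2 scale. For day 7 against day 1, the fit recovered 94.0% of the genes changed 2-fold and all of those changed 4-fold. It called 13 of the other 13982 genes. The noise was drawn independently for each probe set and array, without correlation between genes or outlying arrays. These rates therefore show that the code works and do not estimate power or false calls on the real arrays. Alternatives were quantile normalization, centring on array medians, only the probe sets brighter than the median one, the mean of a gene's probe sets, an intensity trend with robust variances, array weights, the replicate number as a block, a pseudocount of 16, a plain 2-sample test, each array left out in turn, camera with an estimated correlation, and fry. A fit without both arrays numbered 2, which on the first principal component lay nearest to the other age, was added after seeing the data. For arrays the depth is the signal over background: the trp control probe sets read at most 4.76, and genes near that level have no reliable fold change.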

Results

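Transcript levels were measured in Achilles tendons of newborn rats at 2 ages, post-natal day 1 and post-natal day 7, on a whole-transcriptome Affymetrix oligonucleotide array for the rat. Each age had 3 arrays, and each array carried RNA pooled from 2 or more animals, so the p-values measure the spread between pools. The comparison asks which transcripts differ between the newborn tendon and the tendon 1 week into post-natal growth. The median probe set intensity was between 20.5 and 21.1 on each of the 6 arrays, and the probe sets for a bacterial trp transcript, absent from rat RNA and used here as a negative control, read between 3.74 and 4.76. The first principal component held 51.1% of the variance and set the ages apart, with scores of -34.8, -14.8 and -43.8 on day 1 and of 35.0, 14.5 and 44.0 on day 7 (replicates 1, 2 and 3). The small number of arrays limits the precision of every value.

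Of the gene lists fixed beforehand, the 6 with the smallest p-values were those of adipocytes and cartilage, higher on day 7, and those of DNA replication, mitosis, fetal growth and skeletal muscle, lower on day 7 (limma's camera, adjusted p from 8.20e-20 to 1.01e-05; adjusted p from 0.119 to 0.750 with an estimated correlation). Adipoq, which encodes the fat cell hormone adiponectin, was 28.7-fold higher on day 7 (log2 change 4.84, SE 0.33; limma adjusted p = 0.00400), and Plin1, the lipid droplet coat protein perilipin, was 27.5-fold higher (adjusted p = 0.0104), from a mean of 8.49 ± 3.37 on day 1 (SD, n = 3). Myl4, an embryonic myosin light chain, fell by 2.52 on the log2 scale (SE 0.20; adjusted p = 0.00983). Mmp3, which encodes the matrix protease stromelysin, had a mean intensity of 87.8 ± 52.2 on day 7 (SD, n = 3) against 4.88 ± 0.435 on day 1 (adjusted p = 0.0141). The day 1 value lay near the negative control level, so no fold change is given. Scx, the transcription factor that marks tendon cells, had a log2 change of 0.13 (SE 0.15; adjusted p = 0.646).

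**Figure D1:**
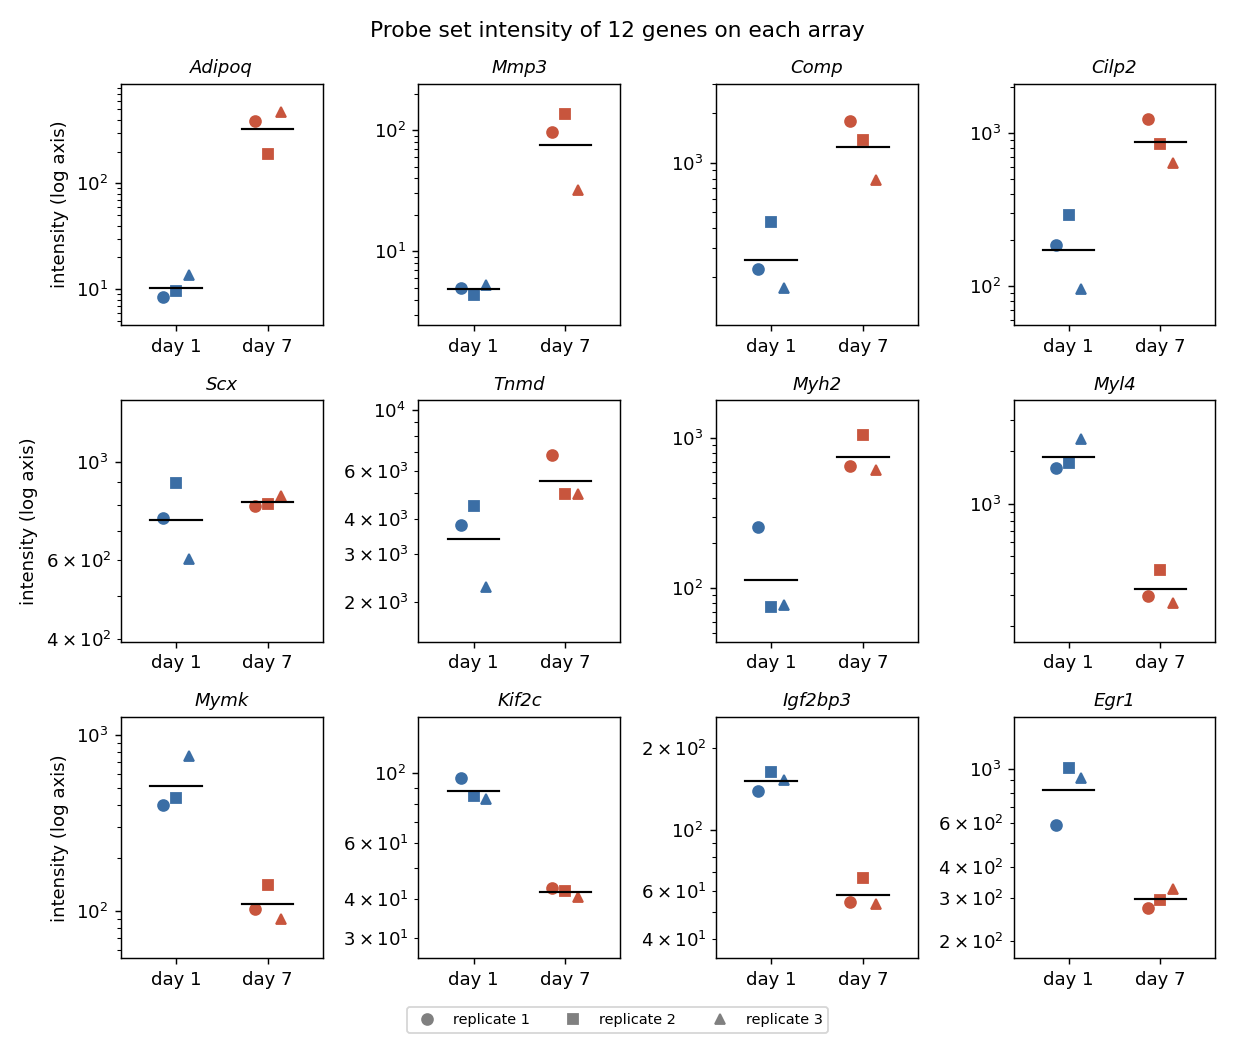
Probe set intensity (log axis, arbitrary units) of 12 genes at day 1 and day 7, with 1 point per array, marker shapes for the replicate number and a bar at the geometric mean of 3 arrays. Adipoq lay between 187.8 and 477 on the day 7 arrays and between 8.47 and 13.5 on the day 1 arrays, while the ranges of Scx overlapped.

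Of 14217 genes with a probe set of their own, 274 were higher and 448 lower on day 7 at an adjusted p under 0.05 (limma), and 114 of the higher and 140 of the lower ones changed at least 2-fold. At an unadjusted p under 0.05 the counts were 1506 and 2411. Among the 31042 probe sets tested, 423 were higher and 668 lower. The share of higher genes among the calls was 38.0% on the values as deposited and 52.4% after quantile normalization, which called 352 higher and 320 lower genes. The count depended on the array left out. It was 26 higher and 37 lower without day 1 replicate 1, 273 and 382 without day 1 replicate 2, 61 and 107 without day 1 replicate 3, 4 and 0 without day 7 replicate 1, 199 and 377 without day 7 replicate 2, and 87 and 79 without day 7 replicate 3. The 4 genes still called without day 7 replicate 1 were Adipoq, Thrsp, Kcna2 and Tspyl4, and 1871 genes were then lower at an unadjusted p under 0.05. With the arrays' median over 33 muscle genes as a covariate, which leaves 3 residual degrees of freedom, 2 genes were higher and 1 lower. The median of the muscle list itself differed with age. It stood at 0.42, 0.06 and 0.59 on day 1 and at -0.39, 0.06 and -0.78 on day 7 (replicates 1, 2 and 3). The covariate thus overlaps with age, and the loss of calls does not show that muscle share accounts for them.

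Of the 10 largest rises among genes whose day 7 arrays all lay above the day 1 arrays, 5 were members of the adipocyte list: Adipoq, Plin1, Pck1, Thrsp and Scd. After Adipoq and Plin1 came Pck1, which supplies glycerol for triglyceride synthesis in fat cells (19.4-fold), and Thrsp, a regulator of fatty acid synthesis (13.8-fold). This order is not fixed, since Plin1 lay below Pck1 with a pseudocount of 16 and below Thrsp with the mean of probe sets. Mmp3 was among the 10, without a fixed rank, since it lay near the negative control level on day 1. Scd, a fatty acid desaturase, had a log2 change of 3.33 (2.93 to 4.04 without 1 array, with the call kept in 2 of 6 such fits), and Gpd1, a glycerol phosphate dehydrogenase, was 9.14-fold higher. Mgst1, a microsomal glutathione transferase, rose 9.34-fold and the secreted carboxypeptidase-like protein Cpxm2 7.69-fold. The lipoxygenase Alox15 had a log2 change of 3.06 (2.41 to 3.67 without 1 array), and its call was lost in each of these 6 fits and with array weights (adjusted p = 0.0551), an intensity trend (0.128), the mean of probe sets (0.0516) and a pseudocount of 16 (0.0926). The adjusted p-values of the 10 ran from 8.95e-04 for Thrsp to 0.0485 for Alox15. Among the 10 largest falls, S100a9, a calcium-binding protein of neutrophils, fell by 2.57 on the log2 scale (adjusted p = 0.0365). Mymk, the membrane protein that drives myoblast fusion, fell by 2.21, and Pdk4, a kinase that restrains glucose oxidation, fell by 2.16. Klk1 fell by 2.38, Col26a1 by 2.29, the lens connexin Gja3 by 2.29, Dpysl5 by 2.24, Slc35g2 by 2.23 and the immediate-early gene Fos by 1.99. The adjusted p-values of these falls lay between 0.00983 for Myl4 and 0.0365 for S100a9. With a pseudocount of 16, the fold changes of several genes, given here with their new log2 changes, shrank by over 1.5-fold. They were Adipoq (3.69), Plin1 (3.46), Pck1 (3.64), Thrsp (2.57), Kcna2 (1.52) and Cidec (1.62). S100a9 (-1.72), Dpysl5 (-1.52), Gja3 (-1.67), Slc35g2 (-1.44) and Igf2bp1 (-0.469) were also among them. Cidec, S100a9, Dpysl5 and Igf2bp1 did not pass. This setting also ended the calls of Mmp3, Scd, Klk1, Fos, Lipe, Lpl, Igf2bp2, Eya1, P4ha1, Omd, Col9a2, S100b, Ngfr, Myh2, Myod1, Myog, Myh8, Ryr1, Dbp, Hlf, Per3, Ier5, Usp18, Ifit2, Ghr, Igfbp2, Fkbp5, Creb3l1, Bmp4, Wnt5b and Mylk. With the mean of a gene's probe sets, fold changes shrank by as much for Plin1 (log2 change 2.97), Thrsp (3.13), Gpd1 (1.83), Cebpa (1.18) and Kcna2 (1.23). The same held for Pdk4 (-1.37), Igf2bp3 (-0.609), Fos (-0.909) and Ghr (0.676), and Fos and Ghr did not pass. Besides Alox15, the calls of S100a9, Igf2bp1, Igf2bp2, Igfbp2, Egfl7, Eya1, Creld2, Manf, Myh8, Mylk, Pfkp, Tef and Tpsb2 were lost in each of the 6 fits without 1 array.

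Of 35 measured genes of DNA replication, 19 fell and none rose, with a median log2 change of -0.68, and adjusted over the list alone 31 fell. The largest of these falls was that of Ccne1, the cyclin of the G1/S transition (3.16-fold lower; adjusted p = 0.0141), and the replicative DNA ligase Lig1 and the helicase subunit Mcm4 fell 1.78-fold and 1.72-fold. Of 35 genes of mitosis, 23 fell and none rose, with a median of -0.88, and adjusted over the list alone 34 fell. The kinesin Kif2c was 2.07-fold lower (adjusted p = 0.0114), the checkpoint kinase Bub1b 2.35-fold, the mitotic kinase Cdk1 2.04-fold and Aurkb 2.13-fold. Against all other genes, limma's camera gave an adjusted p of 1.26e-16 for the replication list, and adjusted p = 0.176 with an estimated correlation. For the mitosis list camera gave 8.20e-20, and adjusted p = 0.457 with an estimated correlation. Over the same arrays the skeletal muscle list had a median change of -0.77 and the adipocyte list one of 1.04.

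Of 23 measured imprinted genes and other genes of fetal growth, 10 fell and none rose, with a median log2 change of -0.54, and adjusted over the list alone 15 fell. Igf2bp3, an RNA-binding protein of fetal tissues, was 2.57-fold lower (SE 0.13 on the log2 scale; adjusted p = 0.0111), and its relatives Igf2bp1 and Igf2bp2 fell by 1.13 and 0.80 on the log2 scale. Dlk1, an imprinted Notch ligand homologue that restrains fat cell differentiation, was 2.07-fold lower, the imprinted amino acid transporter Slc38a4 2.68-fold and the histone methyltransferase Ezh2 1.84-fold. The imprinted growth factor Igf2 and the noncoding RNA H19 had log2 changes of -0.15 and -0.13 (adjusted p = 0.439 and 0.526). The list was lower in camera (adjusted p = 4.05e-07; adjusted p = 0.119 with an estimated correlation). That estimate was -0.0111, below the preset 0.01, so correlation between its genes does not account for the weaker result. The muscle list, with its median of -0.77, moved the same way on these arrays.

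Among 25 measured tendon lineage factors and markers, 4 rose and 2 fell, and adjusted over the list alone 8 rose and 5 fell. The 4 that rose were the cartilage intermediate layer protein Cilp2 (5.05-fold; adjusted p = 0.0282), the integrin-like Itgbl1 (4.86-fold; 0.0180), cartilage oligomeric matrix protein Comp (4.84-fold; 0.0285) and Clec11a, a secreted lectin-like growth factor (4.27-fold; 0.0171). With a pseudocount of 16 the calls of Cilp2 (0.0592) and Comp (0.0617) were lost, and they were kept in 1 and 2 of the 6 fits without 1 array. The 2 that fell were the mechanically responsive transcription factor Egr1 (2.75-fold lower; 0.0180) and the transcriptional coactivator Eya1 (fell by 1.40 on the log2 scale). Tenomodulin, Tnmd, had a log2 change of 0.70 (SE 0.25; adjusted p = 0.163), fibromodulin, Fmod, one of 1.24 (SE 0.34; 0.0888, and 0.0423 with array weights and 0.0419 without day 1 replicate 2), Thbs4 one of 0.31 (SE 0.36; 0.649) and tenascin-C, Tnc, one of -0.04 (SE 0.17; 0.923). The tenocyte homeobox gene Mkx was not analysed here. The median of the list was 0.21, with a camera adjusted p of 0.0546 and adjusted p = 0.818 with an estimated correlation. It passed without day 1 replicate 2 (8.13e-04) and without day 7 replicate 3 (0.0359). The cartilage list, which shares no gene with it, had a median change of 0.74 over the same arrays.

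Of 23 measured collagens, Col15a1 alone rose (1.62-fold, limma adjusted p = 0.0233) and none fell, which was also the count adjusted over the list alone. The list was labelled fibril-forming and fibril-associated, but it also held other collagens, among them Col4a1, Col4a2, Col8a1, Col13a1 and Col15a1 itself. Col1a1 had a mean intensity of 9866 ± 2553 on day 1 and 13729.5 ± 1171 on day 7 (SD, n = 3), with a log2 change of 0.51 (SE 0.19; adjusted p = 0.179). Col1a2 changed by 0.43 (SE 0.16; 0.170) and Col3a1 by 0.19 (SE 0.12; 0.409), both short of the threshold. Col1a2 was the highest of all probe sets on day 7 replicate 1 (18834.1), and saturation of the array at such intensities was not tested. The median of the collagen list was 0.26 (camera adjusted p = 0.0168; adjusted p = 0.818 with an estimated correlation), and the call was lost without day 1 replicate 3 (0.452) and without day 7 replicate 1 (0.0513). Of 24 genes of collagen processing and cross-linking, the prolyl hydroxylase subunit P4ha1 rose (1.81-fold; adjusted p = 0.0336) and none fell, and 3 rose when adjusted over the list alone. Sparc, a collagen-binding matrix protein, had a log2 change of 1.04 (adjusted p = 0.0503), and passed in 7 alternatives, among them quantile normalization (0.0477). The median of that list was 0.32 (camera adjusted p = 5.74e-05; adjusted p = 0.702 with an estimated correlation). On day 1 replicates 1, 2 and 3 the collagen list stood at -0.16, 0.17 and -0.36 and the processing list at -0.15, 0.09 and -0.38, relative to the mean of the 6 arrays, while the muscle list stood at 0.42, 0.06 and 0.59. The tendon lineage list stood at -0.10, 0.18 and -0.48 on these arrays, the cartilage list at -0.45, -0.04 and -0.45 and the proteoglycan list at -0.15, 0.17 and -0.23.

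Of 27 small leucine-rich proteoglycans and elastic fibre genes, decorin, Dcn (1.73-fold; adjusted p = 0.0277), and osteomodulin, Omd (2.94-fold; 0.0243), rose and none fell, and adjusted over the list alone 8 rose and 4 fell. The median was 0.17 (camera adjusted p = 0.0212; adjusted p = 0.818 with an estimated correlation), and the call was lost without day 1 replicate 1 (0.0755), day 1 replicate 3 (0.126) or day 7 replicate 1 (0.0513). Of 29 matrix proteases and inhibitors, Mmp3 alone rose and none fell, against 2 higher and 1 lower adjusted over the list alone. The inhibitor Timp2 had a log2 change of 0.84 (adjusted p = 0.0501), with a pass in 8 alternatives, among them quantile normalization (0.0482), and its other probe set had one of 1.02 (0.0366). The median of the protease list was 0.02 (camera adjusted p = 0.455).

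**Figure D2:**
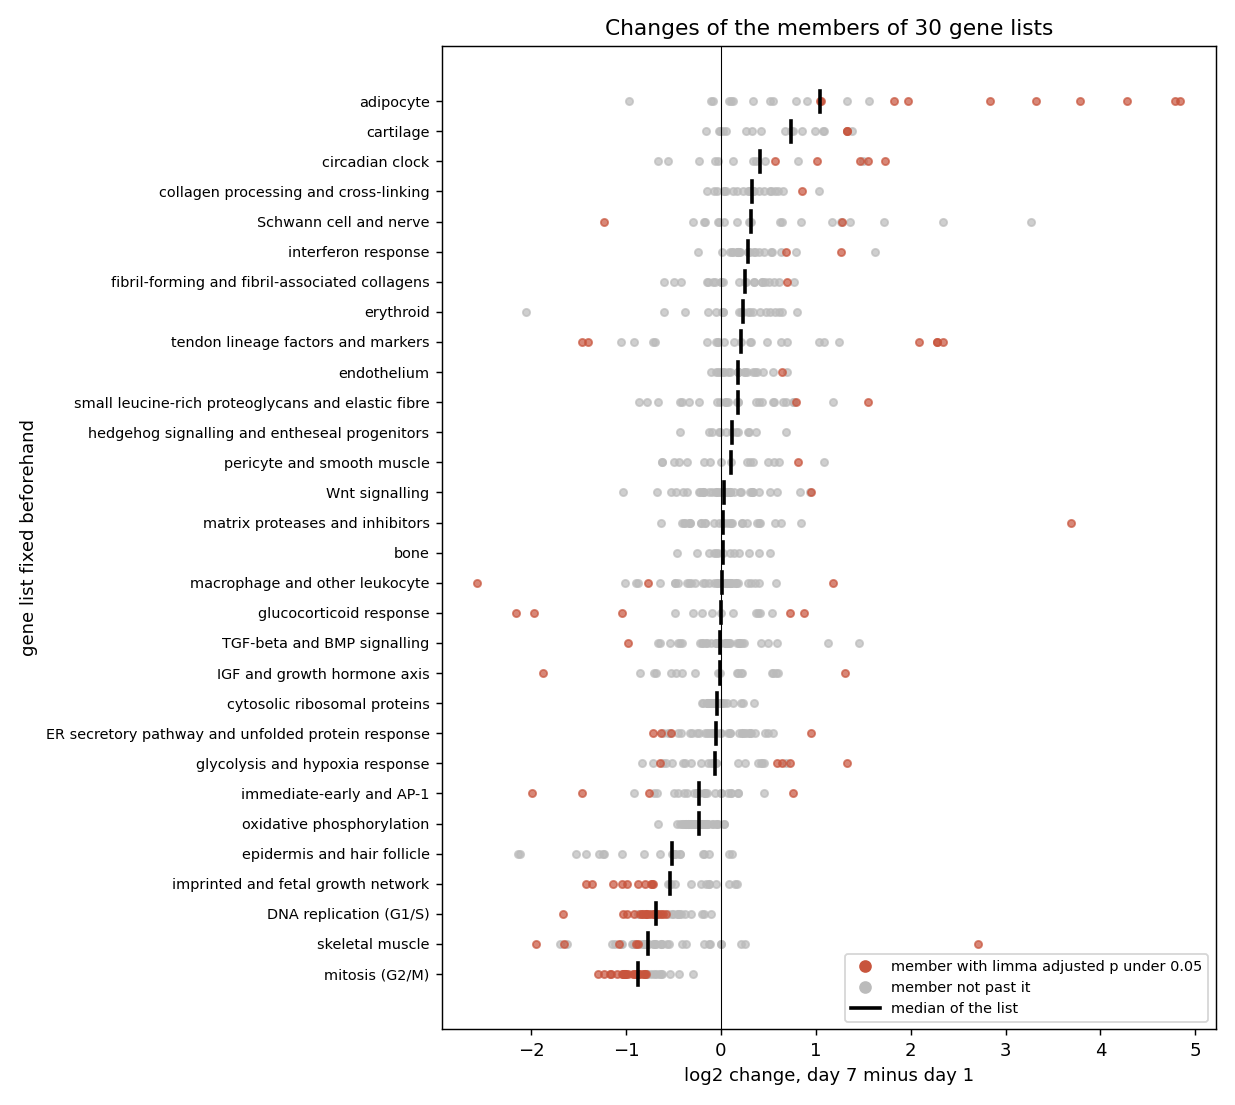
Log2 change from day 1 to day 7 (horizontal axis) of each measured member of 30 gene lists, with members past an adjusted p of 0.05 in red, the others in grey and a black bar at the median. The medians ran from -0.88 for mitosis to 1.04 for adipocytes, and the largest rise in the muscle list was that of Myh2.

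Of 23 adipocyte genes, 10 rose and none fell, with a median log2 change of 1.04, and adjusted over the list alone 17 rose and 1 fell. Besides Adipoq, Plin1, Pck1, Thrsp and Scd, these were Cidec, a lipid droplet protein (log2 change 2.83; 1.62 with a pseudocount of 16, adjusted p = 0.0709), Cfd, the serine protease adipsin (1.97), the transcription factor Cebpa (1.83), and the lipases Lpl (1.05) and Lipe (1.04). The brown fat gene Ucp1 read 4.57 and 5.03 on average on day 1 and day 7, near the negative control level. Cidec also lay low on day 1, with a mean of 6.41. Camera gave an adjusted p of 1.26e-11 for the list, and adjusted p = 0.457 with an estimated correlation. The median of this list lay at -0.45, -0.45 and -0.46 on the day 1 arrays, relative to the mean of the 6 arrays, and at 0.52, 0.13 and 0.90 on day 7 replicates 1, 2 and 3. On the same 3 day 7 arrays the nerve list stood at 0.33, -0.26 and 0.70 and the muscle list at -0.39, 0.06 and -0.78. Day 7 replicate 3 also had the highest 5S ribosomal RNA control probe set (63.2, against 28.9 to 36.3 on the other arrays) and the highest 3'/5' ratio of beta-actin (3.35, against 1.80 to 2.85). The 3'/5' ratio of Gapdh was 2.09 and 2.00 on day 7 replicates 1 and 3, against 1.73 to 1.80 on the other 4 arrays.

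Markers of cartilage had a median log2 change of 0.74 over 19 genes. Cytl1, a cartilage cytokine-like protein (2.52-fold; adjusted p = 0.0190), and the type IX collagen chain Col9a2 (2.52-fold; 0.0377) rose and none fell, and adjusted over the list alone 13 rose. Col2a1, the main cartilage collagen, had a log2 change of 1.33 (SE 0.38; adjusted p = 0.0932), and passed with array weights (0.0397) and without day 1 replicate 2 (0.0399). Camera gave an adjusted p of 1.01e-05, and adjusted p = 0.457 with an estimated correlation. Among 22 endothelial genes Egfl7 rose (1.56-fold; 0.0359) and none fell, also when adjusted over the list alone. The endothelial median was 0.18 (camera adjusted p = 0.00420; adjusted p = 0.7995 with an estimated correlation), and the call was lost without day 1 replicate 3 (0.130).

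Markers of nerve and skin differed between single arrays. Of 21 Schwann cell and nerve genes, the calcium-binding protein S100b rose (2.41-fold; adjusted p = 0.0443) and the neurotrophin receptor Ngfr fell (2.36-fold lower; 0.0483), the same counts as adjusted over the list alone. The median was 0.32 (camera adjusted p = 0.00308; adjusted p = 0.750 with an estimated correlation). Mbp, a major myelin protein, read 1889.8 and 3422 on day 7 replicates 1 and 3 but 81.1 on day 7 replicate 2, and 41.1 to 142.9 on day 1 (adjusted p = 0.178; 0.0137 without day 7 replicate 2). Of 21 genes of epidermis and hair follicle none passed limma, also when adjusted over the list alone or at an unadjusted p under 0.05, with a median of -0.51 (camera adjusted p = 0.269). The keratin Krt1 read 831 on day 1 replicate 1 and at most 13.7 on the other arrays. Without day 1 replicate 1 the epidermis list turned higher on day 7 (camera adjusted p = 0.00313). It passed as lower without day 1 replicate 2 (0.0139) or day 1 replicate 3 (0.0142).

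**Figure D3:**
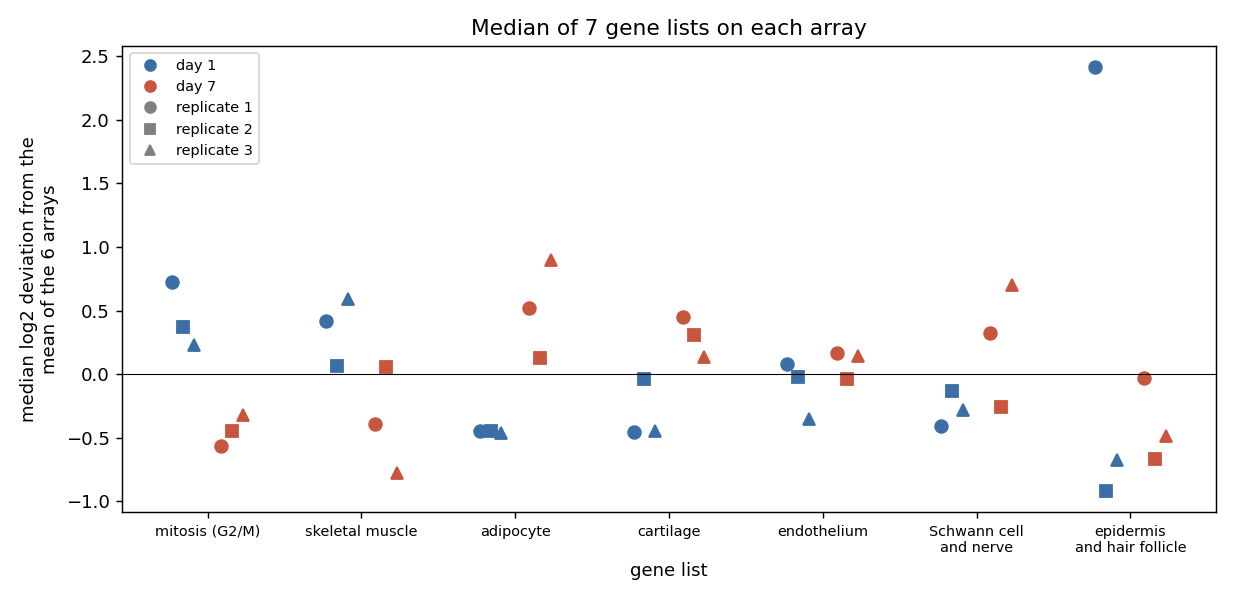
Median log2 deviation of 7 gene lists from the mean of the 6 arrays (vertical axis), with 1 point per array, colours for the age and marker shapes for the replicate number. The epidermis list stood at 2.42 on day 1 replicate 1, and the nerve list at 0.70 on day 7 replicate 3.

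Muscle transcripts were present in every sample, with the skeletal actin Acta1 between 10321 and 13294 on the 6 arrays. Of 39 skeletal muscle genes, 1 rose and 5 fell, with a median log2 change of -0.77, and adjusted over the list alone 1 rose and 28 fell. The adult fast myosin Myh2 was 6.52-fold higher on day 7 (adjusted p = 0.0277). The myogenic regulators Myod1 and Myog were 3.86-fold and 3.15-fold lower (0.0303 and 0.0338), the embryonic myosin Myh3 was 1.84-fold lower (0.0313), and the perinatal myosin Myh8 and the calcium release channel Ryr1 fell by 0.89 and 1.08 on the log2 scale. The slow myosin Myh7 had a log2 change of -0.12 (SE 0.19; adjusted p = 0.762). The list was lower in camera (adjusted p = 5.06e-08; adjusted p = 0.750 with an estimated correlation). Its median stood at 0.42, 0.06 and 0.59 on day 1 replicates 1, 2 and 3, and at -0.39, 0.06 and -0.78 on day 7. Of 41 genes of oxidative phosphorylation none passed, also when adjusted over the list alone, with 0 higher and 6 lower at an unadjusted p under 0.05, 39 of 41 changes below 0 and a median of -0.23 (camera adjusted p = 6.41e-04; adjusted p = 0.818 with an estimated correlation). The smallest adjusted p of that list was 0.116, for the complex I subunit Ndufs1 (log2 change -0.67).

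Of 16 circadian clock genes, 5 rose and none fell, with a median log2 change of 0.42, and adjusted over the list alone 8 rose and 1 fell. The repressor Bhlhe41 was 3.32-fold higher (adjusted p = 0.0141). The clock output factors Dbp (2.76-fold; 0.0306) and Hlf (2.94-fold; 0.0415) rose too, as did Per3 (2.02-fold; 0.0351) and Tef (log2 change 0.57; 0.0483). Bmal1, the activator of the opposite phase, had a log2 change of 0.37 (adjusted p = 0.106). Camera gave an adjusted p of 6.41e-04 for the list, and adjusted p = 0.482 with an estimated correlation. Of 29 immediate-early genes, Fos, Egr1 and Myc fell and Ier5 rose, while adjusted over the list alone 8 fell and 2 rose. Their median was -0.23 (camera adjusted p = 0.0314; adjusted p = 0.523 with an estimated correlation), and the call was lost without day 1 replicate 3 (0.0701) or day 7 replicate 2 (0.138). Of 25 interferon response genes, Usp18 (2.40-fold; 0.0227) and Ifit2 (1.61-fold; 0.0417) rose and none fell, and 4 rose when adjusted over the list alone. The interferon median was 0.29 (camera adjusted p = 2.25e-05; adjusted p = 0.482 with an estimated correlation). This list stood at 0.04, 0.10 and 0.38 on day 7 replicates 1, 2 and 3, highest on the array with the highest 5S ribosomal RNA probe set, beta-actin ratio, adipocyte score and nerve score.

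Several lists that did not pass camera held single genes that changed. In the list of the IGF and growth hormone axis, the growth hormone receptor Ghr rose 2.48-fold (adjusted p = 0.0336) and the binding protein Igfbp2 was 3.68-fold lower (0.0361), the only 2 of 19 past the threshold. In the glucocorticoid response list, Sgk1 and Klf9 rose 1.84-fold and 1.66-fold, while Pdk4, Angptl4 and Fkbp5 fell, among 15 genes. In the glycolysis and hypoxia list 4 of 26 rose, led by Car9, a hypoxia-induced carbonic anhydrase (2.52-fold; 0.0205), and the phosphofructokinase Pfkp was 1.57-fold lower (0.0395). In the list of the secretory pathway and unfolded protein response, Creb3l1, a transcription factor for collagen secretion, rose 1.93-fold (0.0321), and the chaperone Hspa5 was 1.64-fold lower (0.0371) with Creld2 and Manf, out of 38. Bmp4 was 1.97-fold lower (0.0314) as the sole call among 36 genes of TGF-beta and BMP signalling, and Wnt5b rose 1.92-fold (0.0381) as the sole call among 37 of Wnt signalling. Among 40 leukocyte genes, the macrophage receptor Adgre1 rose 2.27-fold (0.0190), and S100a9 and the mast cell tryptase Tpsb2 fell. Mylk rose 1.75-fold (0.0477) as the sole call among 17 pericyte and smooth muscle genes. None of 13 hedgehog genes, 32 cytosolic ribosomal protein genes, 13 bone genes or 21 erythroid genes passed limma; at an unadjusted p under 0.05 the higher and lower genes were 1 and 1, 1 and 0, 1 and 0, and 1 and 2.

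The camera adjusted p-values of these lists were 0.914 for the IGF axis, 0.711 for the glucocorticoid response, glycolysis and ribosomal proteins, 0.973 for the secretory pathway, 0.809 for TGF-beta and BMP, 0.366 for Wnt and for pericytes, 0.864 for leukocytes, 0.306 for hedgehog, 0.696 for bone and 0.318 for the erythroid list. Adjusted over the list alone, the higher and lower genes were 5 and 7 for the IGF axis, 4 and 3 for the glucocorticoid response, 6 and 7 for glycolysis, 2 and 5 for the secretory pathway, 1 and 2 for TGF-beta and BMP, 1 and 0 for Wnt, 1 and 2 for leukocytes, and 3 and 2 for pericytes. None passed in the other 4 lists. The median, the mean and the camera direction did not share a sign for the IGF axis, TGF-beta and BMP, glycolysis, the glucocorticoid response and leukocytes. The erythroid list passed as higher without day 1 replicate 3 (camera adjusted p = 0.0280) and without day 7 replicate 1 (9.53e-05).

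Of the sex-linked genes, too few were measured for a list test. Xist, the noncoding RNA of the inactive X chromosome, read between 1064 and 1851 on day 1 and between 307 and 1006 on day 7 (log2 change -1.22, SE 0.40; adjusted p = 0.132). All 4 probe sets of Xist had log2 changes below 0, and 2 others of them passed, with -1.67 (adjusted p = 0.0440) and -1.78 (0.049997). The Y-linked Eif2s3y read between 23.7 and 28.6 on day 1 and between 40.0 and 109.9 on day 7. Its log2 change was 1.35 (SE 0.32, limma adjusted p = 0.0604). It passed among the brighter probe sets (0.0413), with an intensity trend (0.0464), with array weights (0.0252) and without day 7 replicate 3 (0.0309). The Y-linked Uty had a log2 change of -0.28 (SE 0.21, limma adjusted p = 0.466). The sex of the animals is not given, so the mix of sexes in the pools and age cannot be told apart here. Of the 15 lists that camera called at its preset correlation, none passed with an estimated correlation, and the other 9 ways of parting the 6 arrays into 3 and 3 gave between 9 and 18 called lists.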

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

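Of the tests in this part, those on the adipocyte list, on Myh2 and on the clock genes were chosen after their results were seen. The test of the falling muscle genes with a covariate and the counts over other splits of the arrays were set down before. Among the 9780 probe sets with no gene name, which are part of the probe set counts but of no gene or list above, 87 were higher and 98 lower on day 7 (limma, adjusted p under 0.05), against 1091 calls among all 31042 probe sets. They are given because no gene-level result describes them. The largest changes among them were log2 changes of 3.44 and -2.35.

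The first pattern is the rise of the adipocyte list. Scaling of the arrays is argued against, since the median change stayed at 1.02 or more after quantile normalization. It did so after median centring too, but the array medians lay between 20.5 and 21.1. Centring could therefore hardly move the list and adds no support. A smaller muscle share that lifts every other cell type alike predicts equal shifts of the other lists. The adipocyte median rose by 0.78 more than the endothelial median (SE 0.21, 6 arrays). Both medians had been seen when this comparison was chosen, so it describes the difference and is no independent test. More fat cells in the day 7 samples remain a candidate explanation, which the order of the arrays cannot decide. All 10 called genes were lowest among the day 7 arrays on replicate 2, against 40.9% of the 264 other genes that rose. Genes regulated together keep a common order whether cell number or expression per cell differs. Replicate 2 also had the highest muscle median of the day 7 arrays (0.06, against -0.39 and -0.78 on replicates 1 and 3). Fat cells arising with age and fat carried along in dissection were not tested against each other.

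The second pattern is the fall of the muscle list, on which less muscle in the day 7 samples could bear. Less muscle alone would lower Myh2 as well, whose log2 change was 2.71 (95% interval 1.66 to 3.75). Myh2 was taken up because it had risen, so this interval is no independent test. For the 5 genes that fell, a covariate made of the other 33 muscle genes left 3 with an interval below 0, Myod1, Myog and Myh3, so for these 5 genes tissue share and maturation of the muscle cannot be told apart with 6 arrays. The change of Myod1 went from -1.95 (-2.74 to -1.16) to -0.86 (-1.32 to -0.39) with the covariate.

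The third pattern is the rise of clock output genes, for which another hour of harvest on day 7 could account. It predicts a fall of genes of the opposite phase. The mean change of Bmal1, Npas2, Clock, Cry1 and Nfil3, taken here as such genes, was 0.0152 (SE 0.0703), with members going both ways. Without 1 array, the log2 changes were 0.301 to 0.424 for Bmal1, 0.303 to 0.607 for Npas2 and -0.822 to -0.531 for Nfil3. Those of Clock (-0.131 to 0.00862) and Cry1 (-0.0617 to 0.0227) lay near 0. Whether each of these genes has the opposite phase in this tissue was not tested. Hour of harvest and age cannot be told apart here, as the hour is not given and a difference in it would run with age. The members' opposite signs also keep their mean from deciding it. Age itself stays open and untested.

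With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached, so the gene count cannot pass this test. For genes, 1 of the 10 splits, the real one, gave 722 calls, and the highest of the others gave 0. For lists, 6 of the 10 splits called at least the 15 of the real one, and the highest of the others called 18. The number of lists called at the preset correlation therefore did not set the ages apart from other partings of the arrays. Which lists moved was not compared over the splits.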

How the results depend on the processing

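A called gene was chosen on these same arrays, so its sign is nearly fixed in advance and was not used as a measure of stability. The number of calls moved far. Leaving out 1 array gave 4 to 273 higher and 0 to 382 lower genes, 4 to 140 and 0 to 199 changed at least 2-fold, and 5 to 417 higher and 1 to 577 lower probe sets. The lowest of these counts came without day 7 replicate 1, where 4 of the 722 calls were kept. Dropping an array leaves fewer samples, and why this array weighed most was not tested. Array weights called 538 higher and 897 lower genes, and 905 and 1356 probe sets. A pseudocount of 16 called 182 higher genes, 40 higher and 40 lower by at least 2-fold, and 275 higher probe sets, and kept 431 of the 722 calls. The plain 2-sample test on the same values called 0 genes and 0 probe sets in either direction, with 1220 higher and 1904 lower genes at an unadjusted p under 0.05. Without both arrays numbered 2, a setting added after seeing the data, 230 genes were higher and 607 lower, and 382 were lower by at least 2-fold. Of the 722 calls 380 were kept there. The cause was not tested.

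The replicate numbers were shared by the ages, but same-numbered arrays did not deviate together, with correlations of their deviations of 0.05, -0.25 and -0.14, and day 1 replicate 3 correlated best with day 7 replicate 2 (0.25). With the replicate number as a block, 25 genes were higher and 8 lower, all at least 2-fold, and 31 and 12 probe sets. In that block fit the adjusted p of the lists moved past the threshold for epidermis 0.0212 and tendon lineage 0.0212.

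Of the 15 lists called by camera, 14 or 15 stayed called in each refit of all 6 arrays, and 11 to 15 without 1 array. With an estimated correlation none did, with adjusted p-values of adipocyte 0.457, cartilage 0.457, clock 0.482, collagen processing 0.702, DNA replication 0.176, endothelium 0.7995, collagens 0.818, immediate-early 0.523, fetal growth 0.119, interferon 0.482, mitosis 0.457, oxidative phosphorylation 0.818, nerve 0.750, skeletal muscle 0.750 and proteoglycans 0.818. Fry, which tests a list without the other genes, kept 4 (DNA replication, mitosis, fetal growth and adipocyte) and gave cartilage 0.0889, clock 0.0889, collagen processing 0.284, endothelium 0.499, collagens 0.635, immediate-early 0.0889, interferon 0.119, oxidative phosphorylation 0.499, nerve 0.499, skeletal muscle 0.232 and proteoglycans 0.499. The correlations that camera estimated for the 15 called lists ran from -0.0111 for fetal growth to 0.894 for oxidative phosphorylation. For fetal growth the unadjusted camera p was 6.75e-08 at the preset and 0.00397 with the estimate. The lower estimate cannot explain that loss, so the setting as a whole, and not correlation alone, ended the calls. The immediate-early list missed the threshold with the mean of probe sets (0.0600) and without both arrays numbered 2 (0.0951). The tendon lineage list passed in further settings: quantile normalization 0.0364, each array centred on its median 0.0369, brighter probe sets 0.00737, mean of probe sets 0.0465, intensity trend and robust variance 0.0470, array weights 0.0333, pseudocount of 16 0.0484, without both arrays numbered 2 0.00394. The epidermis list passed with array weights (0.0146).

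Lists far from the threshold changed their direction, with these adjusted p-values. Quantile normalization turned bone 0.817, ribosomal proteins 0.843, secretory pathway 0.549 and IGF axis 0.888. Keeping the brighter probe sets turned secretory pathway 0.549 and leukocytes 0.875. Array weights turned ribosomal proteins 0.839, secretory pathway 0.912 and leukocytes 0.765. A pseudocount of 16 turned secretory pathway 0.980 and leukocytes 0.980. Fry turned IGF axis 0.641 and TGF-beta and BMP 0.809. Leaving out both arrays numbered 2 turned ribosomal proteins 0.941, secretory pathway 0.772, erythroid 0.580, glucocorticoid response 0.885, glycolysis 0.941 and leukocytes 0.580. Without 1 array, adjusted p-values ranged as follows for the lists whose call or direction changed: ribosomal proteins 0.146 to 0.996, endothelium 1.23e-04 to 0.130, epidermis 0.00313 to 0.675, secretory pathway 0.614 to 0.996, erythroid 9.53e-05 to 0.996, collagens 9.62e-05 to 0.452, glycolysis 0.484 to 0.960, IGF axis 0.771 to 0.996, immediate-early 0.0140 to 0.138, leukocytes 0.0667 to 0.996, proteoglycans 4.58e-04 to 0.126, tendon lineage 8.13e-04 to 0.387 and TGF-beta and BMP 0.432 to 0.919.

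Named genes with log2 changes near 0 changed sign: Clock (0.0425 with quantile normalization, 0.0559 with the mean of probe sets, -0.131 to 0.00862 without 1 array), Cry1 (0.0783 with quantile normalization, 0.00524 with array weights, 0.0232 without both arrays numbered 2, -0.0617 to 0.0227 without 1 array), Igf2 (0.0330 with the mean of probe sets), Myh7 (-0.293 to 0.0402 without 1 array), Scx (-0.0127 to 0.273 without 1 array), Thbs4 (-0.120 to 0.620 without 1 array), Tnc (0.0517 with quantile normalization, 0.0427 with array weights, -0.164 to 0.146 without 1 array). None of these genes was called on the values as deposited. Signal over background limits the genes near the negative control level, such as Mmp3 on day 1.

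Of the 97 called genes that the text names, 43 lost their call with a pseudocount of 16. More lost it with the replicate number as a block (82) and without day 7 replicate 1 (93). Quantile normalization ended the calls of Creld2, Hspa5, Igf2bp2, Manf, Ngfr, Pfkp and Tpsb2, the mean of probe sets those of Alox15, Fos, Ghr, Hlf, Ier5, Ifit2, Igf2bp2, Klf9, Mylk, Ngfr and Tef, the intensity trend those of Alox15, Klk1, S100a9 and Scd, array weights that of Alox15 and median centring that of Tef. Of the 6 fits without 1 array, none kept the calls of 14 genes, 1 kept those of C1qtnf7, Cilp2, Col9a2, Creb3l1, Dbp, Dcn, Fkbp5, Fos, Hlf, Hspa5, Ier5, Ifit2, Lpl, Myh3, Ngfr, P4ha1, Per3, Ryr1 and Wnt5b, 2 those of Bmp4, C1qtnf3, C1qtnf5, Car9, Cdh15, Col15a1, Comp, Cytl1, Ezh2, Ghr, Klf9, Klk1, Lipe, Myc, Myh2, Myod1, Myog, S100b, Scd and Tnnt2, and 3 or more those of the others; all 6 kept Adipoq, Kcna2 and Thrsp. Ndufs1 passed without both arrays numbered 2 (0.03005), and Nfil3 there (0.0342), with array weights (0.0425) and without day 7 replicate 2 (0.0498).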

Other observations

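The tests in this part were not planned, and its genes were chosen after their values were seen. Outside the fixed lists, Chrng, the fetal subunit of the acetylcholine receptor, fell by 1.72 on the log2 scale (limma adjusted p = 0.0209), the myoblast cadherin Cdh15 by 1.53 (0.0332), the cardiac and embryonic troponin Tnnt2 by 1.73 (0.0286) and Mybph, a myosin-binding protein, by 1.90 (0.0180). The thyroid hormone receptor Thrb rose by 1.70 on the log2 scale (0.0111). With the mean of a gene's probe sets the changes of Tnnt2 and Thrb were -0.882 and 1.01, and a pseudocount of 16 ended the calls of Chrng (0.0522), Cdh15 (0.0684) and Tnnt2 (0.0598). On the same arrays the skeletal muscle list had a median change of -0.77.

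Of 8 measured genes of the C1q/TNF-related family of secreted proteins, 5 were higher on day 7, against 269 of the 14209 other genes. C1qtnf5 was 2.82-fold higher, C1qtnf2 2.47-fold, C1qtnf7 2.44-fold, C1qtnf1 2.37-fold and C1qtnf3 2.30-fold, with limma adjusted p-values from 0.0141 to 0.0395. Among the day 7 arrays, C1qtnf5 was lowest on replicate 2 and the others of these 5 on replicate 3. The adipocyte, cartilage and muscle lists had median changes of 1.04, 0.74 and -0.77 over the same arrays. A pseudocount of 16 ended the calls of C1qtnf7 (0.0850) and C1qtnf3 (0.0589). Of the 6 fits without 1 array, 1 kept the call of C1qtnf7, 2 those of C1qtnf3 and C1qtnf5, and 4 those of C1qtnf1 and C1qtnf2.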
